A study of Cuscuta campestris with 8 samples.

How the data were processed

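RNA sequencing of polyadenylated RNA was analysed from 8 samples of Cuscuta campestris, 4 of the haustorial region and 4 of the shoot, which are the only groups of the study. Per the labels' protocols, each sample was a pool of tissue from 3 to 4 plants, and RNA was extracted with a plant column kit and then precipitated. The samples were grouped by their titles, which also carry a replicate number from 1 to 4 in each tissue. The header of each file ends in H or S, in step with the tissue in the title for all 8 files.

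The deposited files hold raw read counts per gene, 1 file per sample, as whole numbers that the authors did not scale. STAR version 2.5.2b is listed in the submitters' processing notes. The counting tool, the strand setting, the genome build, the annotation and any read filter are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be assigned to a strand, and reads from near-identical gene copies may have been dropped or split, so fold changes of such copies are uncertain. All 8 files list the same 45825 gene identifiers, each made of the letters Cc and a number, and hold no row without a gene. Of these genes, 5850 had no count in any library.

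The files pair no identifier with a gene name. A table of 45474 genes of the assembly GCA_900332095.2 was compared with them and matched 0 of the 45825 identifiers, and its symbols repeat its locus tags. No gene could therefore be named, placed in the genome or assigned a function. The 55 gene family lists fixed before the data were examined (cell wall enzymes, secreted proteases, transporters, hormone response, cell division, and markers of meristem, epidermis, vascular and green tissue) could not be linked to the identifiers and were not tested. The rule for named genes, also fixed before the data were examined, then limits the text to the 2 identifiers with the largest rise and the 2 with the largest fall among genes that passed the test, had a mean of at least 10 CPM (counts per 1000000 counts of the library) and showed no overlap between tissues. Other genes are described in groups, by direction, size of change, abundance or absence from a tissue.

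Counts were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr function at its defaults (about 10 counts in each of 4 libraries and 15 in total), which left 32855 genes holding 99.9% of the counts of every library. Libraries were scaled with TMM factors, and the tissues were compared with edgeR 4.0.16 (robust quasi-likelihood fit and F test) over all 8 samples, with tissue as the only term. The p-values were adjusted by the Benjamini-Hochberg method over the 32855 genes, and genes with an adjusted p under 0.05 were called. Fold changes are haustorial region over shoot. The standard error (SE) of a log2 fold change was derived from the F test, as its absolute value over the square root of the F statistic. CPM values use the TMM-scaled library sizes unless stated otherwise. Principal components were computed on log2 CPM (prior count 2) of the 500 most variable genes. Single values per library were compared by a two-sided exact permutation test over the 70 arrangements of 8 libraries, for which 0.0286 is the smallest possible p. A gene was counted as detected in 1 tissue only when each of that tissue's libraries had at least 10 counts and each library of the other tissue had 0. A fold against a tissue with no count was bounded by putting 3 counts at that tissue over its 4 libraries together. Ratios and bounds of single genes were taken from summed counts over summed TMM-scaled library sizes. Such bounds, and the exact 95% intervals of count ratios, cover counting error only.

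Library totals ran from 22334600 to 34247925 counts. At these depths 3 counts in a library correspond to 0.0876 to 0.134 CPM. Among genes with at least 1 CPM in both tissues, the median standard error of a log2 fold change was 0.11. The edgeR script was tested on simulated counts with the means, library sizes and dispersions of these data and 200 changed genes. It recovered 37 of 67 genes changed 1.5-fold, 56 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 16 false calls among 174. Only these 200 of 32671 simulated genes changed, in random directions, whereas 65.2% of the tested genes were called in the data. The simulation thus checks the script and does not give the recovery, false calls or scaling error of the real comparison.

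Replicate numbers are shared between the tissues, but no label ties a number to the same plants. Deviations of same-numbered libraries from their tissue means had correlations across genes of -0.06 to 0.04, so the numbers were not treated as pairs and the blocked fit is an alternative. The counts of any 2 libraries of a tissue differed by 5.3 to 28.6 times the sampling variance (chi-square per degree of freedom). This cannot tell separate pools from separate preparations of the same pool. Each library was counted as a separate sample because the labels describe separate pools of plants. They name no sequencing batch.

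Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), other library scalings, no filter and a stricter filter (at least 5 CPM in at least 4 samples), the replicate block, and, for the counts of called genes and the named genes, leaving out each library in turn. Leaving out libraries for other results, thinning of all libraries to the smallest total or the smallest TMM-scaled total, the spread between replicates, the analysis by abundance class, genes with consecutive identifiers and RNA carried over from the other tissue were added after the data were seen. Figures were drawn with matplotlib 3.10.9.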

Results

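Cuscuta campestris is a leafless obligate parasitic plant that attaches to the stem of a host by haustoria, organs through which it takes up water and nutrients. The study grew it in vitro on an artificial host, with no living host plant. Shoot tips of 3 cm were attached to the artificial host, which supplied a liquid medium containing 3 mg per litre of the auxin 1-naphthaleneacetic acid and 1 mg per litre of the cytokinin 6-benzylaminopurine. The plants spent 2.5 days under light enriched in far-red and 12.5 days under full-spectrum light. At 15 days after inoculation, haustorial regions with healthy holdfasts were freed of shoots and visible meristems, and new shoots were taken after the 5 mm of stem next to the haustorial region had been discarded. Polyadenylated RNA was sequenced from 4 pooled samples of each tissue.

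Total counts averaged 26201020 ± 3482638 (SD, n = 4) in haustorial libraries and 27324700 ± 5167909 in shoot libraries, a difference within the spread between libraries (exact permutation p = 0.714). Log2 expression across genes correlated at 0.978 to 0.985 between haustorial libraries, 0.986 to 0.989 between shoot libraries, and 0.777 to 0.805 between libraries of different tissues. These are correlations across genes, which are not independent replicates. The first principal component of the 500 most variable genes held 98.1% of their variance and separated the tissues, with scores of 69.9 to 77.0 for the haustorial region and -75.9 to -71.7 for the shoot. The second component held 0.672%.

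The comparison addressed which genes differ in expression between the haustorial region, which contacts the artificial host, and new shoots of the same in vitro system. No other tissue was sampled, and visible meristems had been removed from the haustorial region. Differences due to haustoria therefore cannot be told apart from those due to meristems, tissue age or contact with the medium. Of 32855 genes tested, 21412 (65.2%) differed between the tissues, 10248 higher and 11164 lower in the haustorial region (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With a change of at least 2-fold, 3068 genes were higher and 5029 lower. At 4-fold the numbers were 1060 and 2520, at 8-fold 531 and 1518, and at 32-fold 197 and 599. The ratio of lower to higher genes thus went from 1.64 at 2-fold to 3.04 at 32-fold. The 4 haustorial and 4 shoot values did not overlap for 19839 genes (60.4% of those tested), against 2.86% by chance. With libraries scaled by their totals alone, the median log2 fold change of all tested genes moved by -0.19, and the share of called genes that were higher in the haustorial region was 33.1% instead of 47.9%.

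**Figure D1:**
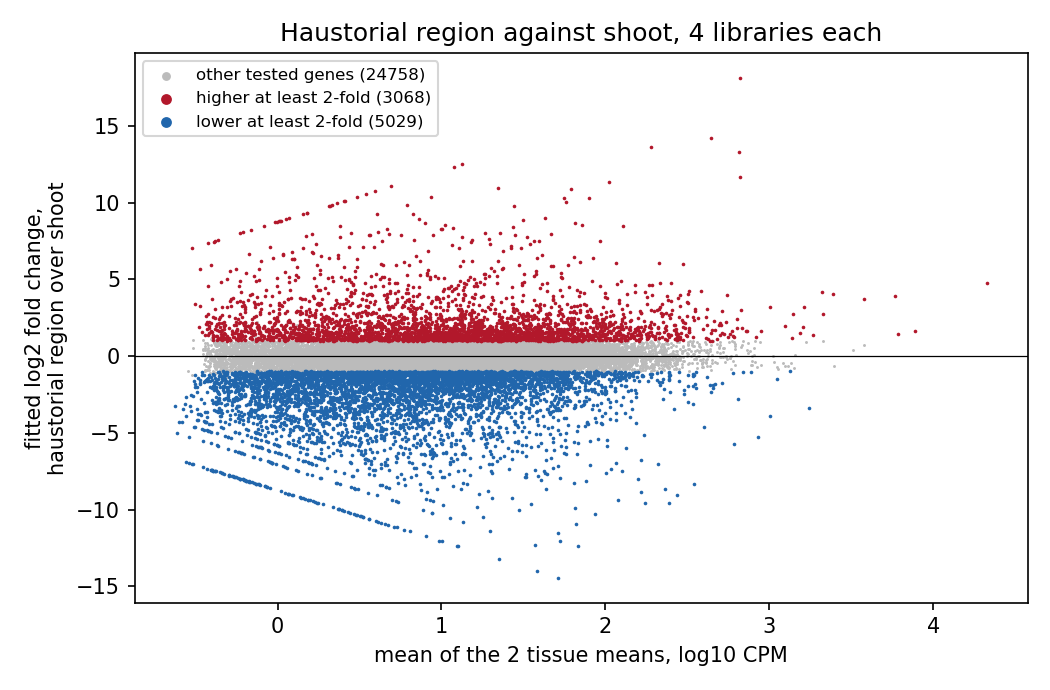
Fitted log2 fold change (haustorial region over shoot, vertical axis) of each tested gene against its mean expression (log10 CPM, horizontal axis). Red points are the 3068 genes called higher and blue points the 5029 genes called lower in the haustorial region by at least 2-fold; the diagonal rows of points at the edges are genes with few or no counts in 1 tissue.

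The balance of higher and lower genes differed between abundance classes, given here as counts without a test because genes are not independent replicates. Among the 1558 genes with a mean of at least 100 CPM over the 8 libraries, 311 rose and 157 fell by at least 2-fold in the haustorial region. Among the 17651 genes of 10 to 100 CPM, 1311 rose and 1655 fell. Among the 11561 genes of 1 to 10 CPM, 1170 rose and 2516 fell, and among the 2085 tested genes under 1 CPM, 276 rose and 701 fell. At 8-fold the pattern was alike, with 56 genes higher and 35 lower in the most abundant class and 240 higher and 827 lower between 1 and 10 CPM. Every class kept the direction of its larger count with RLE, upper-quartile and library-size scaling, with DESeq2 and after thinning all libraries to the smallest total. With library-size scaling the most abundant class held 263 higher and 198 lower genes.

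**Figure D2:**
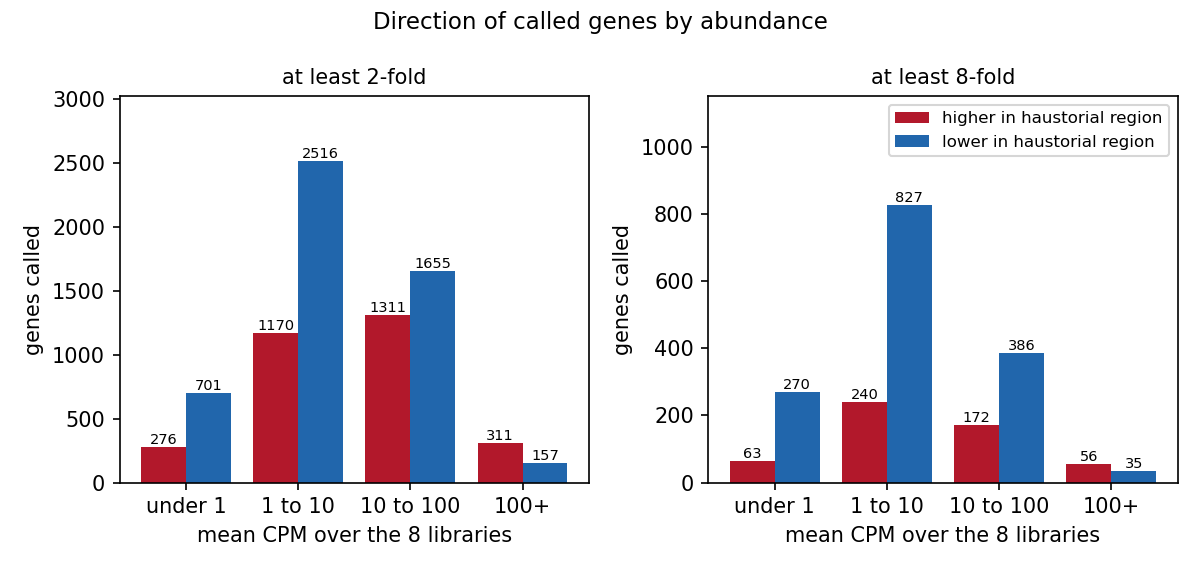
Number of genes called higher (red) and lower (blue) in the haustorial region (vertical axis, genes), by mean CPM over the 8 libraries (horizontal axis), for changes of at least 2-fold (left) and at least 8-fold (right). Lower genes outnumber higher genes in each class under 100 CPM, and higher genes outnumber lower genes at 100 CPM and above (311 against 157 at 2-fold).

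Haustorial libraries concentrated more of their counts in few genes. The most abundant gene of each library held 3.83% ± 0.69 (SD, n = 4) of the counts in the haustorial region and 0.441% ± 0.114 in the shoot. The 100 most abundant genes of each library held 18.2% ± 1.3 and 10.2% ± 0.6, and the 1000 most abundant held 38.7% ± 1.3 and 30.3% ± 0.6. The effective number of genes (the exponential of the Shannon entropy of the count shares) was 8201 ± 656 in the haustorial region and 13117 ± 319 in the shoot. With every library thinned to the smallest total, 35855 ± 147 genes had a count in haustorial libraries and 36477 ± 109 in shoot libraries. The shares of the top gene and of the top 100, the effective number and the thinned gene number did not overlap between tissues in any library, each with an exact permutation p of 0.0286, the smallest the design allows (0.0286 after adjustment over these 4 measures).

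**Figure D3:**
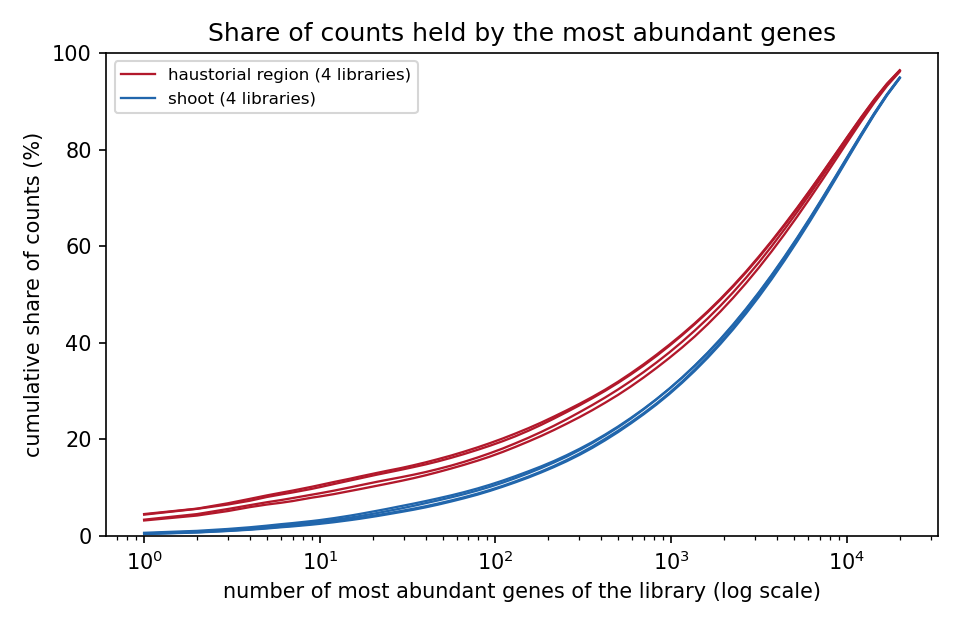
Cumulative share of a library's counts (vertical axis, percent) held by its most abundant genes, ranked within the library (horizontal axis, number of genes, log scale), 1 line per library. The 4 haustorial lines (red) lie above the 4 shoot lines (blue), at 16.8% to 19.6% against 9.65% to 10.9% for the top 100 genes.

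The most abundant transcript of the haustorial region stood at 41041 ± 8372 CPM (SD, n = 4) there and at 1532 ± 318 CPM in the shoot, a log2 fold change of 4.74 ± 0.24 (SE; edgeR adjusted p = 1.34e-09). The most abundant transcript of the shoot by mean CPM was a different gene, though it was not the top gene of every shoot library. It was also higher in the haustorial region, at 11790 ± 1457 CPM against 3728 ± 1560 CPM in the shoot, a log2 fold change of 1.66 ± 0.26 (SE; edgeR adjusted p = 1.26e-04). Both were picked by abundance after the values were seen. The lists of the 100 most abundant genes of each tissue, by mean CPM, shared 47 genes. Of the haustorial list, 76 genes were called higher in the haustorial region, 14 lower and 10 were not called, and they held 18.1% ± 1.3 of haustorial and 7.37% ± 0.76 of shoot counts. Of the shoot list, 56 genes were lower in the haustorial region, 23 were higher and 21 were not called, but together they held 14.3% ± 0.9 of haustorial and 10.2% ± 0.6 of shoot counts. Because each list was picked on its own tissue's level, the direction of most of its calls is not independent evidence. The 3068 genes called higher by at least 2-fold took up 27.5% ± 1.9 of haustorial and 7.08% ± 0.77 of shoot counts. The 5029 genes called lower took up 3.56% ± 0.16 of haustorial and 16.3% ± 0.4 of shoot counts, and these shares also follow from how the genes were selected.

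The gene with the largest rise was Cc021807. It was measured at 1321 ± 301 CPM (SD, n = 4) in the haustorial region, with 949 CPM in the lowest library, and had 0 counts in all shoot libraries, which together held 109298801 counts. This makes it at least 51616-fold higher in the haustorial region (edgeR adjusted p = 1.2e-09). Cc034231 had 887 ± 362 CPM in the haustorial region and 0.0439 ± 0.0515 CPM in the shoot, from 87641 and 5 counts. The ratio was 20862, with a 95% interval of 8939 to 64252 for counting error (edgeR adjusted p = 7.3e-08). Of the 5 counts, 3 were in shoot replicate 3, and without that library the ratio was 38542 (10669 to 318257). The largest falls were those of Cc027972 and Cc016340, which had 0 counts in all haustorial libraries, which together held 104804080 counts. In the shoot, Cc027972 was at 103 ± 24 CPM and Cc016340 at 77.0 ± 18.1 CPM, at least 3373-fold and at least 2517-fold lower in the haustorial region (edgeR adjusted p = 6.1e-07 for each). What these genes encode is not known from the sources used here.

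Few genes were detected in 1 tissue only. By the criterion of at least 10 counts in each library of a tissue and 0 in each library of the other, 33 genes were seen only in the haustorial region and 111 only in the shoot. With at least 1 CPM in each library of a tissue and under 0.1 CPM in each of the other (scaled to total counts), the numbers were 50 and 214. Neither criterion was repeated at equal TMM-scaled totals, which summed to 97975034 in haustorial and 116608628 in shoot libraries. At an equal scaled level, a count of 0 was thus easier to reach in the haustorial region, which favours shoot-only genes. Most of the 33 and 111 genes had low levels, with a median of 2.34 CPM for the haustorial genes and 1.74 CPM for the shoot genes. At least 10 CPM was reached by 3 of the haustorial genes and 12 of the shoot genes. The median lower bound of their fold was 94.0 for the haustorial and 56.6 for the shoot genes. Of these genes, 32 and 106 passed the expression filter. All of these were called, which follows from how they were picked and is not independent evidence.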

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

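Thinning, and leaving out libraries for results other than the counts of called genes and the fitted changes of the named genes, were chosen after the data were seen. The count of 21412 called genes ranged from 17122 to 22148 over the alternatives, and it was 20659 with the replicate block, where 20445 of the original calls remained. Leaving out each library in turn gave 19980 to 21282 calls, kept 92.1% to 95.2% of the original ones and turned no called gene's direction. The stricter filter tested 24920 genes and lowered the genes changed at least 2-fold from 8097 to 5184, of which 2032 were higher and 3152 lower, since it removes genes of low level. Library-size scaling turned the fitted sign of 57 called genes, none of which was then called in the other direction, and raised the ratio of lower to higher genes at 2-fold to 2.55. Requiring at least 1 CPM in 1 tissue and under 0.1 CPM in the other, in place of 10 counts and 0, gave 50 genes for the haustorial region and 214 for the shoot. Minimums of 5 and 20 counts gave 47 and 24 haustorial and 138 and 85 shoot genes. Leaving out each library gave 34 to 44 and 112 to 154. These cannot fall below the numbers with all libraries, since leaving out a library removes a condition, so they say nothing about stability. The first principal component held 90.1% of the variance over all tested genes, 98.8% over the 100 most variable genes and 96.5% with a prior count of 0.5. It held 97.9% to 98.4% with each library left out. The share of counts in each library's own most abundant genes stayed larger in the haustorial region in each alternative. The number of detected genes stayed lower there. With each library left out, the excess in the share of each library's own top 100 genes was 7.56 to 8.49 percentage points. The difference in detected genes was then -674.5 to -556.2 with libraries thinned to the smallest total (-621.5 with all libraries) and -729.6 to -575 without thinning (-651), and it was -469.8 with all libraries thinned to equal TMM-scaled totals. Their exact p was the smallest possible throughout and says nothing about stability. The 4 named genes kept their direction and calls in each fit that tested them. Same-numbered libraries showed no shared deviation (0 of 8 libraries correlated best with their own number), so the replicate block tests no known pairing. The gene list alternatives were not run, because the lists could not be linked to the identifiers. Depth limits statements on genes near 3 counts per library, about 0.1 CPM.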

Other observations

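The tests in this part, other than the splits of the libraries, were chosen after the tissue comparison had been seen, and those of the scaling and of the 8-fold changes after the values they rest on. The criteria for the filter at 5 CPM and for genes with a log2 fold change between -0.1 and 0.1 were also not set beforehand. Genes with consecutive identifiers changed together more often than by chance. Of 1930 pairs of genes with consecutive identifiers that were both called with at least a 2-fold change, 1326 (68.7%) changed in 1 direction and 604 in opposite ones. Shuffling the genes 1000 times gave a mean of 1588 pairs with both genes called (at most 1696), of which 53.0% on average and at most 56.3% changed in 1 direction. The excess thus lies both in the number of such pairs and in their shared direction. There were 50 runs of at least 4 consecutive identifiers that were all called in 1 direction by at least 2-fold, against a mean of 9.66 and at most 19 in the shuffles. Of the 50 runs, 42 were lower and 8 higher in the haustorial region. The shuffled runs were not counted by direction. Lower genes were more numerous at 2-fold (5029 against 3068), so the 42 against 8 is no evidence that lower genes cluster more. The longest run, of 7 identifiers, was no longer than the longest in the shuffles (8). The correlation of log2 fold changes across genes fell with the distance between identifiers, from 0.12 at a difference of 1 to 0.05 at 2 and 0.02 at 5, and lay within the shuffled range at 10 and beyond.

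Each tissue held little of the RNA most specific to the other. For each library, the 10 genes with the lowest level in the other 3 libraries of its tissue were taken from those with at least 100 CPM in the other tissue. In shoot libraries these genes were at 0.00829% to 0.0398% of their haustorial level, and in haustorial libraries at 0.0633% to 0.151% of their shoot level. With 20 genes the ranges were 0.256% to 0.359% and 0.202% to 0.319%. For RNA with the mean profile of the other tissue these are upper limits, since any own expression of the genes adds to them; RNA from a part of that tissue that lacks these genes is not bounded.

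On chance as a source of the tissue difference, none of the other 34 splits of the 8 libraries into 4 and 4 called a gene with edgeR or with limma-voom; with edgeR, 49 to 2105 genes had an unadjusted p under 0.05 in those splits, against 22453 in the real one. The real split, with 21412 genes, was the 1 of 35 with a result as large, and the highest other split had 0. The same held for the 8097 genes with at least a 2-fold change (1 of 35 splits, 0 in the highest other). For both counts this argues against a chance split of the libraries only as far as 35 splits can, since 1 of 35 is the smallest possible share. Every other split puts both tissues in each arm, which adds the tissue difference to the residual, so its 0 is no estimate of the number of false calls.

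The first pattern weighed is the excess of genes lower in the haustorial region. Making the 2-fold counts equal would need a shift of all log2 fold changes by 0.21, while the TMM, RLE and upper-quartile scalings differ by 0.02, which argues against the choice among them, and after thinning the ratio was 1.64 with equal library totals and 1.64 with equal TMM-scaled totals, which argues against depth. Among genes with a mean of at least 10 CPM the ratio at 2-fold was only 1.12 (1622 higher, 1812 lower). Most of the 2-fold excess thus lay in genes of lower mean. Between 1 and 10 CPM 1170 genes were higher and 2516 lower, and under 1 CPM 276 and 701. Among genes with at least 5 CPM in at least 4 libraries the ratio was 1.55 (2032 higher, 3152 lower). That filter can be passed through 1 tissue alone, so it cannot exclude genes of low mean level as the source. Whether low counts themselves produce the excess stays open. At 8-fold the ratio among genes with at least 10 CPM was 1.85 (228 higher, 421 lower). This argues against genes of low mean level as the whole source of the larger changes. Such a mean can also be reached through 1 tissue alone, so counts near the floor in the other tissue are not excluded. The excess lay between 10 and 100 CPM (172 higher, 386 lower) and was reversed at 100 CPM and above (56 higher, 35 lower). A difference between tissues in total messenger RNA, which these scalings remove, and a biological difference in how many genes the shoot with its meristems uses, were not tested.

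The second pattern is the shared direction of consecutive identifiers. A chance order is excluded, since the correlation of 0.12 lay above all 1000 shuffles (-0.02 to 0.02), and it was 0.12 among genes with at least 10 CPM as well. If 1 transcript were split over 2 gene models, both parts would show equal fold changes. Only 37.6% of same-direction pairs had log2 fold changes equal within the 95% interval of their difference, against 33.3% of random same-direction pairs. This argues against split models as the source of all these pairs. It cannot exclude them for a part, since the shuffles also gave a mean of 842 same-direction pairs, against 1326 in the data. A candidate explanation is that consecutive identifiers mark neighbouring and often duplicated genes, which could be tested with the gene sequences and positions not used here.

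The third pattern is the larger spread between haustorial replicates. The biological coefficient of variation was 0.143 in the haustorial region and 0.0997 in the shoot, a ratio of 1.43 that was not tested against chance. Thinning gave a ratio of 1.44 with equal library totals and 1.45 with equal TMM-scaled totals, and leaving out each library in turn gave 1.36 to 1.59. A varying share of shoot tissue in the haustorial pools would leave genes of equal level in both tissues unaffected, but the ratio was 1.61 in the 4016 genes with a log2 fold change between -0.1 and 0.1, called or not, which argues against it as the whole source (1.55 in 10754 genes within 0.5 and not called, a set that itself depends on the spread). Varying amounts of other tissue, such as older stem, and differences between holdfasts may contribute and were not tested.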
